A study of Mus musculus with 4 samples.

How the data were processed

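SOX2 ChIP-seq was made from the cortex of 2-month-old male wild-type mice. Per the labels' protocols, 0.3 g of tissue was crosslinked with a long-arm crosslinker and then formaldehyde, the chromatin was sheared to fragments of 200 to 600 bp, and SOX2 was pulled down with a rabbit antibody. There were 3 IP samples and 1 input sample, each placed in its group by its title. A further label field names SOX2 as a transduced factor in all 4 samples, the input included, which does not match the wild-type tissue of the protocol, and it was not used for grouping. The input has no table of its own here and enters through columns of the IP tables.

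The submitters' processing notes name Bowtie 1.0.0, HOMER 4.7 and the mm10 build. Per the file headers, the authors called peaks separately in each IP library with HOMER findPeaks in factor mode and the input as control. The headers give the filters: at least 4-fold over the input, at least 4-fold over the surrounding 10 kb, a Poisson p-value of at most 0.0001 and a false discovery rate of 0.001. Per the file headers, the signal used here for strength is the authors' normalized tag value of a peak, scaled to a library total of 10000000 tags. The tag totals in the peaks were deposited as whole counts for IP library 2, and as a signal scaled to the input total for IP libraries 1 and 3. The folds are the authors' ratio of IP to input tags, with the input set to 0.5 tags where it was lower. The peak score was deposited as the number of tags left after a cap of 1 tag per bp in IP libraries 1 and 2 and of 2 in IP library 3, per the file headers. The focus ratio, the fraction of a peak's tags placed as its centre predicts, had a median of 0.735 ± 0.00346 over libraries (SD, n = 3) and is the authors' value. The p-values of single peaks are the authors' and were not used beyond their own filter. Score, fold and normalized tags are properties of single peaks and were used to describe, rank or filter peaks.

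The depth was 36330529, 32492927 and 41875666 tags in IP libraries 1, 2 and 3, and a peak needed at least 14, 13 and 16 tags there. A typical peak held about 20 tags (median 22.0, 20.0 and 22.0, computed from the normalized tags and the library total). Weak peaks are therefore close to the threshold and may be missed in another library by counting noise alone. In IP library 3 the input filter removed 22.8% of putative peaks, against 15.5% and 14.8% in libraries 1 and 2.

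Peaks that overlapped by at least 1 bp were merged in chains, and a merged region holding peaks of all 3 libraries was called reproducible; these had a median length of 201 bp and a longest of 516 bp. The strength of a region in a library is that of its strongest peak there. Gene spans came from a RefSeq gene table of the GRCm38.p6 assembly, whose coordinates are those of mm10, with 21631 protein-coding genes. That table gives neither strand nor exons, and no genome sequence was used here. The planned search for 15 sequence motifs, the SOX motif among them, was therefore not run, and neither was the repeat filter for named genes. For the same reason the planned distance to transcription starts became the distance to either end of a gene span, and regions were assigned to the nearest protein-coding gene span within 50 kb (distance 0 inside a gene). The 1 region on chromosome Y was left out of gene comparisons.

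Overlap and position were compared with the same peaks or regions moved at random by 10 to 500 kb, in 100 draws. For each of 19 gene lists fixed before the data were examined, the number of members with a reproducible region was compared with 10000 random lists of protein-coding genes. These were matched gene by gene on the decile of the length of sequence that lies nearest to the gene, in a two-sided permutation test with Benjamini-Hochberg adjustment over the lists. The astrocyte list was compared with each other list by shuffling list membership 10000 times within deciles of gene surroundings, in a two-sided permutation test adjusted in the same way. A Fisher's exact test, which takes no account of gene surroundings, was run beside it. The same chance test was applied to 11 further lists and to 143 gene families of at least 15 members with a common symbol stem, each set adjusted on its own. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

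Named genes were chosen by a rule set before the data were examined. It took the 20 genes whose reproducible region had the highest mean rank of normalized tags within its library, with at least 4-fold enrichment in each. It added the up to 4 strongest members of each list, and always Sox2, Gfap, Vim and Nes. Coordinates are given for the 5 strongest. Some genes that the rule names are not reported here.

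The list test was tested on simulated data with the 21631 genes. Of 200 null lists of 30 genes, 1.5% had p below 0.05. In 100 further lists, 40% of members on average were given a region, beside those that already had one by random placement. Of these lists, 96% had p below 0.05. Regions were placed at random along the chromosomes and members were drawn independently, so lists of neighbouring genes were not simulated. For 200 null lists of genes with wide surroundings the matched test gave 1.5%, whereas a test without matching gave 100%. The overlap step, run on 17729 simulated peaks per library, returned 20.1%, 50.0% and 80.0% for true shares of 20%, 50% and 80%. Centres of shared simulated peaks were shifted by far less than a peak's width. The simulation therefore checks the computation, and larger offsets between libraries were not simulated.

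Alternatives covered the overlap rule, peak strength, fold, number of peaks, chance model, window, annotation, assignment distance, matching of random lists and omission of each library. Samples were not compared between conditions, since the design has a single tissue and condition.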

Results

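SOX2, a transcription factor of the SOX family that marks neural stem cells and is also made by astrocytes, was mapped on chromatin of the mouse cortex by chromatin immunoprecipitation and sequencing (ChIP-seq). In ChIP-seq, DNA bound by a protein is pulled down with an antibody, sequenced and compared with the unselected DNA of the same kind of chromatin, the input. The tissue came from 2-month-old male wild-type mice of the C57BL/6 strain, and 3 immunoprecipitated (IP) libraries and 1 input library were made. The series as a whole concerns deletion of SOX2 from astrocytes and recovery after brain injury, and none of the 4 samples is labelled as injured or as lacking SOX2. The design therefore implies comparing each IP library with the input, the IP libraries with each other, and the enriched regions with the genes around them. IP library 1 held 36330529 tags (sequenced reads placed on the genome) and 17730 peaks. IP library 2 held 32492927 tags and 17628 peaks, and IP library 3 held 41875666 tags and 15891 peaks. The strength of a peak is given in normalized tags, the authors' value per peak, which scales each library to a total of 10000000 tags. The input entered through the values that the authors gave for each peak. Nothing in the labels says whether the 3 IP libraries came from separate animals or separate chromatin, so the spread between them may be technical.

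The comparison of each IP library with the input asked where in the cortex genome the SOX2 pull-down was enriched. The input was the only control and no sequence motif was searched, so other pulled-down chromatin could not be told apart from SOX2 binding. By mean rank over the 3 libraries, the strongest region assigned to a gene lay near Sox21, a SOX family transcription factor that also acts in neural progenitors. This region, on chromosome 14 from 118230322 to 118230672, held 48.9 ± 9.76 normalized tags (mean and SD, n = 3) and lay 2.74 kb outside the gene. The peak of IP library 2, from 118230520 to 118230672, did not overlap that of IP library 3, from 118230322 to 118230480, and both are joined only through the peak of IP library 1, so the region was not reproducible when peaks had to overlap by 0.5 of both lengths. Its enrichment over the input also varied, with 42.6-fold, 31.3-fold and 125-fold in IP libraries 1, 2 and 3. Phlpp1, a phosphatase that acts on AKT, followed with 44.1 ± 5.20 normalized tags at a region inside the gene on chromosome 1 from 106199731 to 106199901. Cdk12, a kinase of the tail of RNA polymerase II, held 43.1 ± 5.87 inside the gene and 0.259 kb from 1 of its ends, on chromosome 11 from 98202609 to 98202774. A region 0.0755 kb outside Mtf2, a Polycomb-like protein, on chromosome 5 from 108065502 to 108065667, held 41.1 ± 4.05. Klf13, a zinc finger transcription factor, had its strongest region 18.3 kb outside the gene on chromosome 7 from 63957153 to 63957311, with 41.6 ± 7.0 normalized tags. All coordinates are on the mm10 build.

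The next strongest genes held 33.7 to 39.6 normalized tags. Among them were Sparcl1, which encodes a synapse-organising protein secreted by astrocytes, with 37.7 ± 8.37 inside the gene, and Cst3, which encodes the protease inhibitor cystatin C, with 36.2 ± 3.80 at 9.91 kb outside it. The ATP synthase subunit gene Atp5pb (38.3 ± 4.23) and the gene Qrich1 (37.9 ± 7.19) carried their strongest regions within 0.1 kb of a gene end. Regions inside the gene were found for Fam13c (39.6 ± 5.65), Thbs3 (38.4 ± 8.05), Arhgef10l (37.5 ± 9.92), Ttyh1 (36.5 ± 5.69), Fgfrl1 (35.7 ± 4.48), Alpk1 (35.0 ± 7.54), Sh3gl2 (34.7 ± 6.18), Mical2 (34.4 ± 6.41) and Sfxn5 (33.8 ± 1.91). The region assigned to Dph5 (33.7 ± 5.02) lay 43.3 kb from that gene. The region assigned to Pamr1 (35.1 ± 7.96) lay inside Pamr1 and 37.3 kb from Slc1a2, the main glutamate transporter of astrocytes, a neighbour that was chosen after its position was seen. Assignment to the nearest gene does not show which gene a region acts on.

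Sox2 itself carried 2 regions found in all 3 libraries. The stronger spanned 1 end of the gene, on chromosome 3 from 34649899 to 34650137, with 10.1 ± 1.95 normalized tags (n = 3). Gfap, which encodes the intermediate filament of astrocytes, had 1 such region, 1.38 kb outside the gene, on chromosome 11 from 102898474 to 102898695, with 7.73 ± 0.890. Vim, another intermediate filament gene, was assigned peaks in each library, but none of them overlapped across all 3, and the strongest per library held 4.13, 5.54 and 4.78 normalized tags. Nes, which encodes the progenitor filament nestin, was assigned 1 peak in IP library 2, with 4.92 normalized tags, and 1 in IP library 3, with 5.25.

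**Figure D1:**
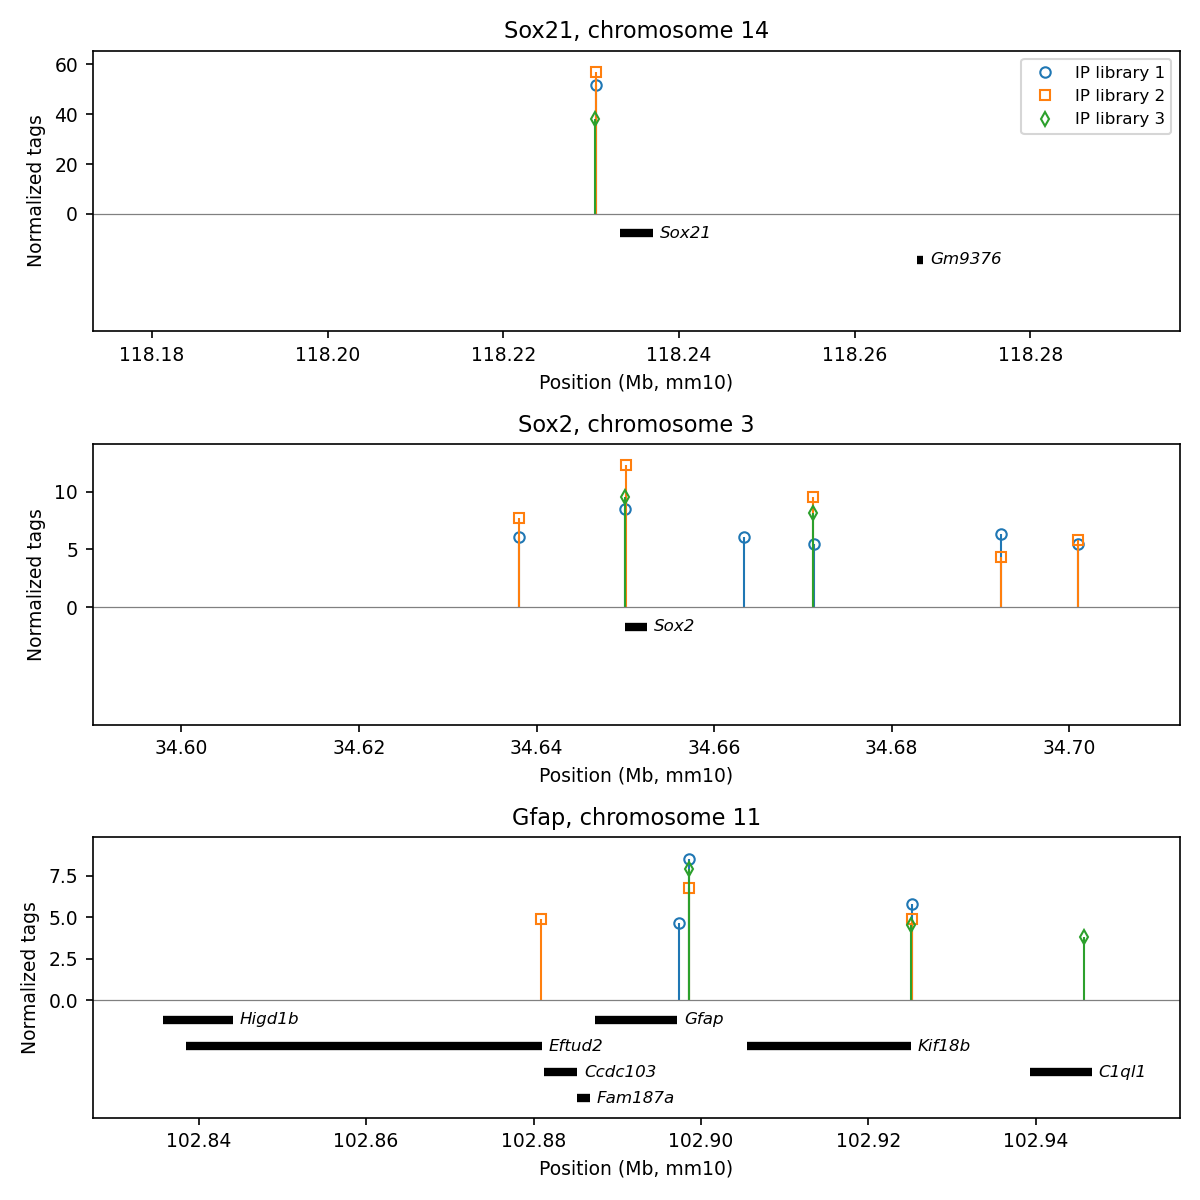
Peaks of the 3 IP libraries within 60 kb of Sox21, Sox2 and Gfap, with position in Mb on mm10 on the horizontal axis and normalized tags on the vertical axis. Each symbol is the peak of 1 library and black bars are protein-coding gene spans; the Sox21 peaks reach 38 to 56.9 normalized tags, while the peaks near Sox2 and Gfap stay at or below 12.3.

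Over all peaks of a library, the median enrichment over the input was 12.2-fold, 11.9-fold and 10.6-fold in IP libraries 1, 2 and 3, a mean of 11.6 ± 0.856 (SD, n = 3). The median peak held 5.82 ± 0.499 normalized tags, and the peaks together held 1.36%, 1.35% and 1.06% of the tags. These folds are the authors' values. In 13% to 13.6% of peaks the input was at a floor of 0.5 tags, and the fold of those peaks depends on that floor.

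The comparison of the IP libraries with each other asked which regions were found again. After merging, 27083 regions held a peak of at least 1 library, and 9334 of them (34.5%) held peaks of all 3, called reproducible regions here. In 280 of the reproducible regions, the one near Sox21 among them, peaks were linked in a chain with no base common to all 3 libraries. Another 5496 held peaks of 2 libraries and 12253 a peak of 1 library. Reproducible regions were stronger, with a median over regions of 7.63 normalized tags and 15.3-fold enrichment, each averaged over the region's libraries first, against 4.62 tags and 7.71-fold for regions of 1 library. Of the peaks of IP libraries 1, 2 and 3, 51.6%, 51.9% and 57.6% overlapped peaks of both other libraries, a mean of 53.7 ± 3.38% (SD, n = 3). The same peaks moved at random by 10 to 500 kb did so in 0.191% to 0.216% of cases on average, and in at most 0.289% in any of 100 draws. With only the stronger 0.5 of each library's peaks, 5786 regions were found in all 3, and with only peaks of at least 8-fold enrichment 5623.

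The share found in all 3 libraries rose with peak score, from 13.8 ± 0.883% in the weakest decile of a library's peaks to 97.3 ± 0.486% in the strongest decile (SD, n = 3). Across the regions shared by a pair of libraries, log2 tag values had a Pearson correlation of 0.835 to 0.843 and a Spearman correlation of 0.776 to 0.788. These correlations run across regions, which are not independent replicates. Over all regions shared by a pair, the differences between libraries were 0.922 to 0.960 times the variance of counting noise, in regions that had to pass the threshold in both. At regions of at least 10 normalized tags they were 1.20 to 1.30 times that variance, at a like level in all 3 pairs.

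**Figure D2:**
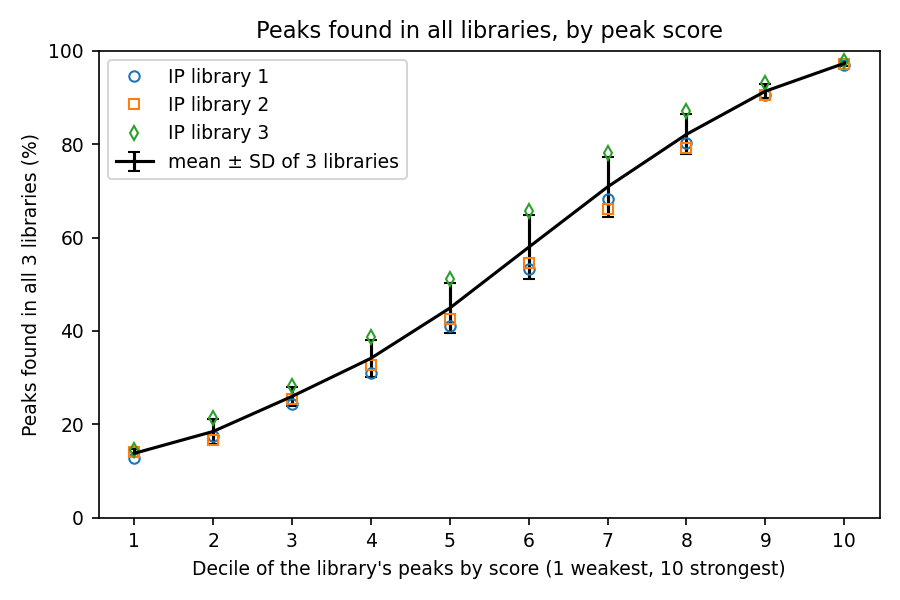
Percent of each IP library's peaks that overlapped peaks of both other libraries (vertical axis), by decile of peak score from weakest to strongest (horizontal axis). Symbols are the 3 libraries and the line with bars their mean ± SD, which climbs from 13.8% to 97.3%.

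The comparison of the reproducible regions with gene positions asked where these regions lie relative to genes. Regions were concentrated at gene ends: 1847 of 9333 (19.8%) had their centre within 1 kb of an end of a protein-coding gene, 4.51 times the 4.39% of regions moved by 10 to 500 kb (highest of 100 draws 4.83%). The sources used here give no strand, so a gene end is either its start or its finish. A further 44.5% lay inside a gene and over 1 kb from its ends, against 48.3% of moved regions, and 18.7% lay outside genes at up to 50 kb, against 25.8%. The remaining 16.9% lay over 50 kb from every protein-coding gene, against 21.5%. All 3 of these shares were below the lowest of the 100 draws. The shares of all positions add up to 100%, so the excess at gene ends lowers the others, whose deficits are not separate results. The strongest decile of peaks lay at gene ends less often than the middle deciles, with 15.6 ± 0.865% against 23.5 ± 0.241% in decile 5 of 10, the highest (SD, n = 3). The weakest decile was at 18.9 ± 2.27%, and these differences were not tested. The strongest far regions held 40.8 ± 8.50 normalized tags at 322 kb from Plod2, 38.9 ± 7.15 at 367 kb from Tcf4 and 38.7 ± 5.51 at 159 kb from Rnd3, and these genes were chosen after their values were seen.

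**Figure D3:**
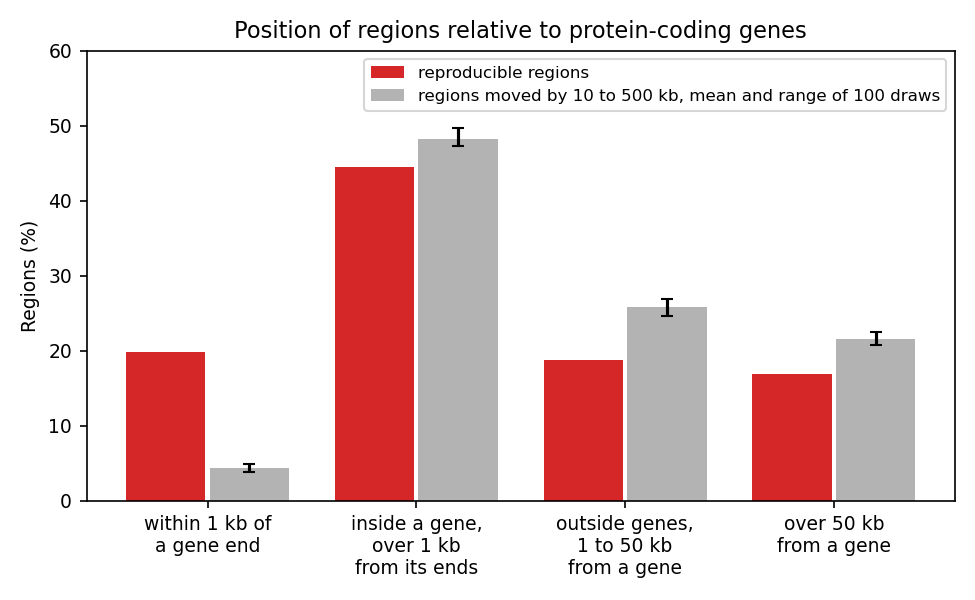
Percent of the reproducible regions in 4 positions relative to protein-coding genes (vertical axis), beside the same regions moved by 10 to 500 kb, whose bars are the mean and whose lines are the range of 100 draws. The reproducible regions exceed the moved ones only within 1 kb of a gene end, with 19.8% against 4.39%. The shares add up to the whole, so this excess lowers the others.

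The comparison with gene lists asked which kinds of genes carried SOX2 regions. In all, 7753 regions (83.1%) were assigned to 4873 of 21631 protein-coding genes. Genes that mark astrocytes carried regions far more often than matched random genes: 28 of 30 had at least 1, against 8.81 in random lists, a ratio of 3.18 (adjusted p = 0.0019, permutation test). Sparcl1 and Gli3, an effector of Hedgehog signalling, had the strongest, with 37.7 ± 8.37 and 34.1 ± 3.54 normalized tags (SD, n = 3). Kcnj10, the potassium channel Kir4.1, had 32.0 ± 7.56, and Mlc1, a membrane protein of astrocyte end-feet, had 27.0 ± 5.25. The exceptions were Clu, with peaks in 2 libraries, and S100b, with no peak in any of the 3 libraries.

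Genes of neural stem and progenitor cells also carried regions more often, in 23 of 30 against 8.92 in random lists, a ratio of 2.58 (adjusted p = 0.0019, permutation test). Among the strongest were the RNA-binding protein gene Msi1 (28.2 ± 0.702), the Notch effector Hes5 (26.1 ± 4.65) and the nuclear receptor gene Nr2e1 (26.3 ± 7.92). The share of astrocyte markers with a region was not shown to differ from that of this list (adjusted p = 0.25, permutation of list membership within deciles of gene surroundings). It was higher than that of each of the other 17 lists, with adjusted p from 0.00036 to 0.0307 by the same permutation test, chosen after the data were seen, genes shared by both lists left out. An adjusted p of 0.0019 comes from the smallest p that the random lists can give, 0.0002.

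Among signalling pathways, the Notch list had regions at 17 of 30 members against 7.75 in random lists, a ratio of 2.19 (adjusted p = 0.0038, permutation test). Beside Hes5, its strongest members were Nrarp, a feedback inhibitor of Notch (27.2 ± 4.40), the coactivator gene Maml2 (25.1 ± 3.33) and Lfng, which modifies Notch receptors (18.4 ± 3.88). With only regions over 5 kb from every gene end, a setting chosen after the data were seen, the ratio was 1.61 and the adjusted p 0.403, the highest over its 14 alternatives (lowest 0.00127). The list of FGF and EGF receptor signalling had regions at 18 of 30 against 9.84, a ratio of 1.83 (adjusted p = 0.0114, permutation test). It was led by the transcription factor gene Etv5 (27.2 ± 3.28), the feedback inhibitor Spry4 (21.6 ± 4.94), the receptor gene Fgfr1 (18.4 ± 3.17) and Spred1 (16.7 ± 1.20). Its adjusted p was above 0.05 under 4 of 14 alternatives, from 0.0627 to 0.403, among them regions over 1 kb from every gene end.

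The Wnt list, with 18 of 38 members against 11.5, and the Hedgehog list, with 10 of 18 against 5.56, did not pass the test (adjusted p = 0.0746 and 0.0811, permutation test). Tcf7l1 (28.2 ± 2.18), Lgr4 (21.2 ± 5.81), Apc (19.7 ± 2.22) and Wnt7a (18.5 ± 4.80) were the strongest of the former, and Gli3, Cdon (31.7 ± 5.56), Ptch1 (24.2 ± 3.20) and Gli2 (20.1 ± 1.46) of the latter. The Wnt list passed under 8 of 14 alternatives, including each omission of 1 library (ratio 1.57 to 1.59). The BMP and TGF-beta list had 16 of 32 against 11.1 (adjusted p = 0.173, permutation test), with Id4 (22.2 ± 4.14), Bmpr2 (12.3 ± 1.63), Smad6 (11.4 ± 1.31) and Id3 (11.4 ± 2.14) leading. JAK-STAT and gp130 signalling had 9 of 24 against 6.28 (adjusted p = 0.435, permutation test), led by Socs3 (23.3 ± 3.50), an inhibitor of that pathway, Lif (12.3 ± 2.14), Cntfr (11.3 ± 1.30) and Stat5b (8.08 ± 1.55).

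The SOX family itself had regions at 10 of 19 members against 5.06 in random lists, a ratio of 1.98 that did not pass (adjusted p = 0.0689, permutation test). Beside Sox21 these included Sox13 (26.7 ± 4.69), Sox8 (23.4 ± 3.83) and Sox9 (21.9 ± 0.751), the last a regulator of astrocyte development. With random lists matched on gene length instead, the ratio was 2.86 and the adjusted p 0.0038, and over all 14 alternatives the adjusted p ran from 0.0038 to 0.256, below 0.05 in 3 of them.

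Genes that rise when astrocytes react to injury did not stand apart, in tissue that is not labelled as injured. The reactive gliosis list had regions at 10 of 37 members against 8.82 in random lists (adjusted p = 0.787, permutation test). Its strongest members were Socs3, the endothelin receptor gene Ednrb (20.1 ± 4.27), Chil1 (10.5 ± 0.20) and the proteoglycan gene Bcan (9.0 ± 2.32). A stronger region, with 32.9 ± 4.87 normalized tags, lay 50.4 kb from Ednrb, just beyond the 50 kb limit of assignment. Vim and Nes were among the 27 members without a reproducible region. Without IP library 3 the list had 9 of 37 against 10.3, below random instead of above, and it passed under 0 of 14 alternatives (ratio 0.872 to 1.51).

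Markers of the other cell types of the cortex did not pass the test either. Neuron markers had regions at 8 of 32 against 10.7 in random lists (adjusted p = 0.532, permutation test), among them Fezf2 (35.0 ± 6.00), a factor of deep-layer neurons, Grin2b (13.4 ± 1.01) and Map2 (10.7 ± 1.42). Neurogenic transcription factors had 8 of 24 against 6.36 (adjusted p = 0.640, permutation test), among them Neurog1 (19.9 ± 4.21), Pou3f2 (17.9 ± 4.40) and Pou3f3 (14.4 ± 5.29). Oligodendrocyte lineage markers had 9 of 27 against 6.74 (adjusted p = 0.537, permutation test), led by Sox8, Olig1 (17.0 ± 1.73), Bcas1 (13.3 ± 4.25) and Olig2 (11.7 ± 3.02). Microglia markers had 3 of 23 against 4.81 (adjusted p = 0.575, permutation test), namely Sall1 (9.75 ± 3.65), Ly86 (6.94 ± 1.39) and P2ry12 (5.21 ± 0.827). Endothelial and mural markers had 5 of 23 against 7.14 (adjusted p = 0.553, permutation test), with Erg (8.68 ± 2.97) and Pdgfrb (6.61 ± 1.65) the strongest. Without IP library 1, microglia markers had 5 of 23 against 5.34, and with only the stronger 0.5 of peaks endothelial and mural markers had 1 of 23 against 5.06. With regions of at least 2 libraries, neuron markers had 14 of 32 against 13.9 and oligodendrocyte markers passed with 15 of 27 against 9.18 (adjusted p = 0.0452, permutation test), while with the gene body and 5 kb on each side the latter had 5 against 6.60; matched on gene length, neurogenic factors had a ratio of 1.92 instead of 1.26.

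Hepatocyte genes, a control list from another tissue, had regions at 3 of 30 members against 6.12 in random lists (adjusted p = 0.351, permutation test), namely Ttr (13.8 ± 1.24), Pck1 (9.09 ± 2.71) and Tat (4.44 ± 0.542). Pluripotency genes, targets of SOX2 in embryonic stem cells, had 4 of 21 against 5.08 (adjusted p = 0.787, permutation test). These were Lin28a (9.66 ± 1.45), Tdgf1 (9.05 ± 1.46), Fgf4 (6.86 ± 1.90) and Klf4 (5.03 ± 1.32). Without IP library 1 the pluripotency list had 7 of 21 against 5.61, a ratio of 1.25 instead of 0.788, and over its 14 alternatives the ratio ran from 0.245 to 1.25. The ratio of hepatocyte genes, 0.490, ran from 0.312 to 0.734, and neither list passed under any alternative.

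Among genes that most cells use, ribosomal protein genes had regions at 10 of 35 members against 4.16 in random lists, a ratio of 2.40 (adjusted p = 0.0479, permutation test). Among the 4 strongest, the regions of Rps19 (30.4 ± 3.84), Rps7 (28.3 ± 5.73) and Rps6 (13.3 ± 2.40) lay at or within 1 kb of the gene. That of Rpl11 (13.9 ± 3.95), which ranked above Rps6, lay 41.7 kb outside it. With regions over 1 kb from every gene end the adjusted p was 0.605, with only 1.53 members expected, and it was above 0.05 under 6 of 14 alternatives in all, from 0.0624 to 1. The list passed under the other 8. Among these were regions of at least 2 libraries, with 17 of 35 against 6.48 (ratio 2.62, adjusted p = 0.00127, permutation test). Cell cycle genes had 14 of 36 against 7.37, a ratio of 1.90 (adjusted p = 0.0513, permutation test), led by Mcm3 (28.4 ± 1.56), Rb1 (18.1 ± 1.37), Plk1 (17.9 ± 2.49) and Top2a (17.0 ± 2.34). That list passed under 7 of 14 alternatives, each omission of 1 library included (ratio 1.81 to 1.95), but had a ratio of 1.22 with regions over 1 kb from every gene end. Altogether 5 of the 19 lists lay above random lists at an adjusted p below 0.05 and 0 lay below, while 9 had an unadjusted p below 0.05. Some of the 5 lists share members with a region, so they are not separate results. Notch1, Hes1 and Hes5 were in the Notch and the stem and progenitor lists. The FGF and EGF list shared Fgfr1 and Egfr with the stem and progenitor list, and Fgfr2 and Fgfr3 with the astrocyte list.

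**Figure D4:**
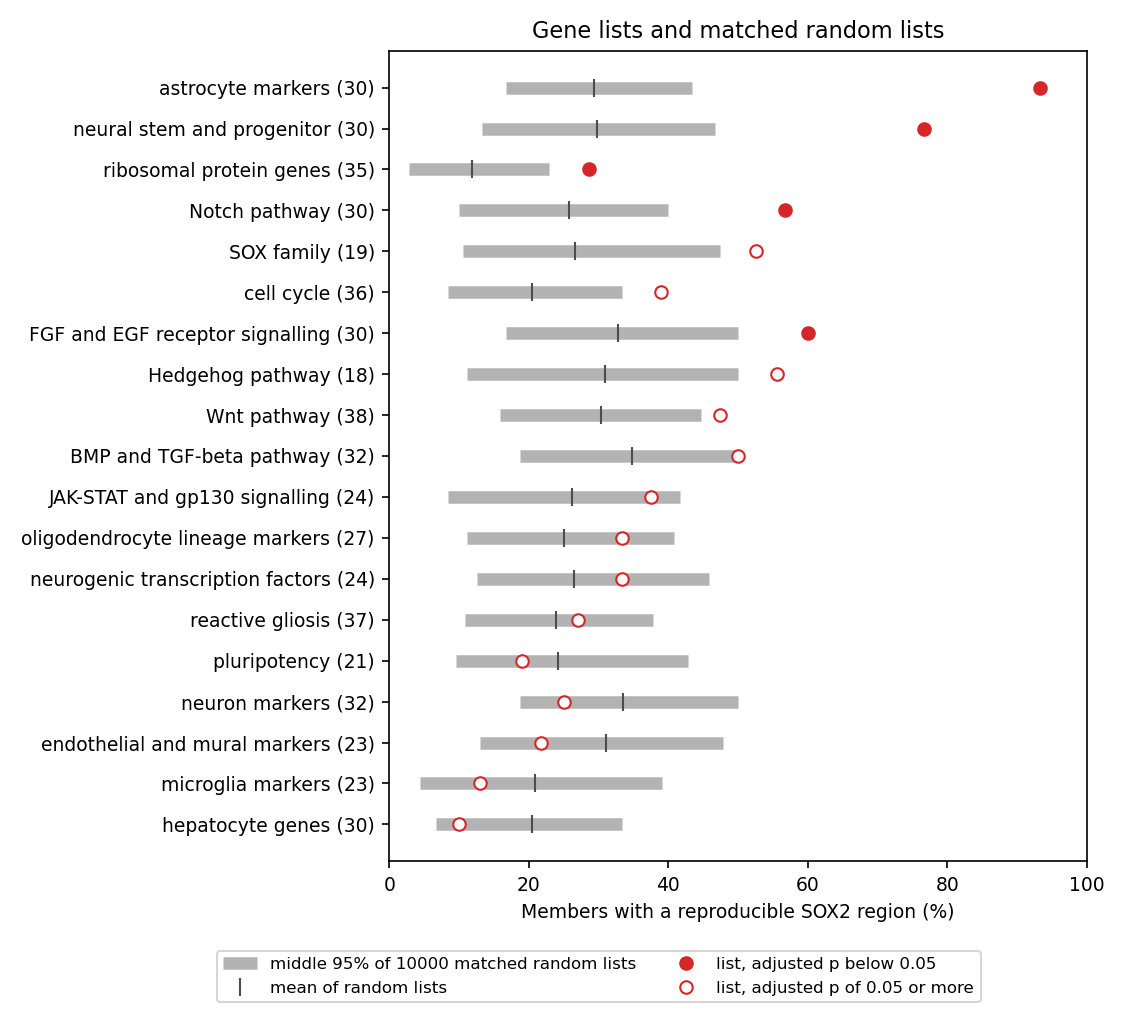
Percent of the members of each of the 19 gene lists with a reproducible region (circles, horizontal axis; number of members in parentheses), with the mean (tick) and the middle 95% (grey bar) of 10000 matched random lists. Filled circles passed the test; astrocyte markers lie at 93.3% and neural stem and progenitor genes at 76.7%, while reactive gliosis genes lie at 27.0% and neuron markers at 25.0%.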

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

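Settings chosen after the data were seen were a base shared by peaks of all 3 libraries, the assignment by nearest gene end, the omission of chromosome X, regions over 5 kb from any gene end, and the omission of sensory and defence gene families. Astrocyte markers and neural stem and progenitor genes passed the test under all 14 alternatives, with ratios of 2.48 to 4.14 and 2.26 to 3.37. The share at gene ends stayed above the highest random draw under all of its alternatives. The cause of the changes that follow was not tested.

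Reproducible regions numbered 5786 with the stronger 0.5 of peaks and 5623 at 8-fold or more, by construction fewer, and 9054 with a base shared by all 3 libraries. The share of peaks shared was 44.0% with overlap of 0.5 of both lengths, 49.3% with centres within 100 bp, 62.5% with the stronger 0.5 of peaks and 50.2% at 8-fold or more. With 1 library left out it was 64.0% to 66.2%, since a peak then has to recur in 1 library only. The chance share was 0.129% for peaks placed anywhere on the chromosome, against 0.201%. The correlation of strength was 0.783 by ranks, 0.825 in the stronger 0.5 of peaks and 0.835 to 0.843 with 1 library left out. Enrichment over the input, as the mean of the 3 library medians, was 14.3-fold in reproducible regions.

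The number of lists above random was 10 with regions of at least 2 libraries, 3 by nearest gene end and 3 with regions over 5 kb from gene ends. Regions of at least 2 libraries brought past the threshold the SOX family (ratio 1.75), Wnt (1.56), BMP and TGF-beta (1.44), oligodendrocyte (1.63) and cell cycle (1.82) lists. Assignment within 10 kb did so for Wnt (1.70) and cell cycle (2.14), within 100 kb for cell cycle (1.91), and matching on gene length for the SOX family (2.86) and cell cycle (1.90). Regions over 1 kb from gene ends did so for the SOX family (2.55) and Wnt (1.82), those over 5 kb for Wnt (1.93), and the stronger 0.5 of peaks for Wnt (1.98). With 1 library left out, Wnt (1.57 to 1.59) and cell cycle (1.81 to 1.95) passed each time.

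FGF and EGF receptor signalling no longer passed by nearest gene end (1.70), over 1 kb (1.70) or 5 kb (1.48) from gene ends, or with the stronger 0.5 of peaks (1.86). Ribosomal protein genes no longer passed by nearest gene end (2.23), over 1 kb (1.97) or 5 kb (1.56) from gene ends, with the stronger 0.5 of peaks (2.43), without chromosome X (2.30) or without sensory and defence families (2.15). Notch no longer passed over 5 kb from gene ends (1.61). The astrocyte list lay above the same number of other lists, 17, by Fisher's exact test and by the permutation test, which was chosen after the data were seen. The motif alternatives were not run, as no genome sequence was used here. No paired analysis was possible because the input is a single sample.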

Other observations

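The lists and gene families of this part, and the tests of tissue expression and of copy number together with gene density, were chosen after the data were seen. Genes by which astrocytes handle glutamate, GABA and potassium carried reproducible regions without exception, 16 of 16 against 5.17 in matched random lists (adjusted p = 0.0022 over 11 lists, permutation test), although 8 of them are also in the astrocyte list. They included the cystine-glutamate exchanger gene Slc7a11 and the glutamate dehydrogenase gene Glud1. Semaphorins, plexins, slits, robos and netrins, which guide axons, had regions at 26 of 40 against 15.5 (adjusted p = 0.0044, permutation test), with Robo1 and Sema5b the strongest. Circadian clock genes had 12 of 20 against 5.68 (adjusted p = 0.00715, permutation test), with Rora and Cry2 leading, and genes of cholesterol and fatty acid synthesis 13 of 24 against 5.76 (adjusted p = 0.00715), with the regulator Srebf2 and the desaturase Fads2 leading. Ephrins and their receptors, which also guide axons, did not pass, with 7 of 22 against 6.94 (adjusted p = 1, permutation test). In the same permutation test, neither did secreted synapse factors (9 of 14 against 5.56, adjusted p = 0.218), glycolysis (6 of 19 against 3.88, adjusted p = 0.461), Hox genes (2 of 39 against 4.81, adjusted p = 0.379), or ependymal and cilium genes (5 of 20 against 6.12, adjusted p = 0.851). Adrenergic, muscarinic and purinergic receptors (8 of 23 against 6.20, adjusted p = 0.631) and voltage-gated sodium and calcium channels (7 of 26 against 10.6, adjusted p = 0.338) did not pass that permutation test either.

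Among 143 gene families, olfactory receptors had regions at 3 of 1110 members against 161 in random lists (adjusted p = 0.00715, permutation test), namely Olfr159, Olfr987 and Olfr1513. At the same adjusted p, vomeronasal receptors had 0 of 355 against 73.7, secretoglobins 0 of 40 against 7.83 and cytochrome P450 genes 6 of 99 against 22.5. The Pramel (1 of 46 against 8.62), Defb (0 of 42 against 6.24) and Tas (0 of 38 against 5.84) families also lay below, with adjusted p from 0.0286 to 0.0465 in the permutation test. The Rpl family of ribosomal protein genes lay above, with 16 of 53 against 6.54 (adjusted p = 0.0286, permutation test), while the Rps family, which also holds kinases such as Rps6ka5, did not pass (16 of 44 against 8.11, adjusted p = 0.0629). Most of the families below random lie in clusters, so neighbouring members are not independent. The gene with the most regions was Msi2, with 18 and a gene span of 379 kb. It was followed by Ntm with 15 (span 969 kb), Rora with 14 (735 kb) and Npas3 with 12 (824 kb). Regions were also assigned from the surroundings, so the sequence they came from was longer, 451 kb for Msi2 and 1053 kb for Ntm. The number of regions was not tested against gene length.

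A pattern to follow up is that astrocyte markers carried regions at 28 of 30 members while reactive gliosis genes did not stand apart. No sample is labelled as injured, so the latter leaves open whether SOX2 lies at gliosis genes in reacting astrocytes. Peaks at the outer ends of gene spans do not account for the astrocyte count. Of its members, 26 had a region over 1 kb from every gene end, against an upper bound of 11 in the middle 95% of random lists. Starts of transcripts inside a gene span are not given by the sources used here, so peaks at those are not excluded. Gene length does not account for the astrocyte count either, since 28 members compare with an upper bound of 13 for random lists matched on length. Expression in the tissue as a whole, as the only cause, was predicted to raise neuron markers too. Of these, 8 of 32 had a region, below their upper bound of 16. That prediction was written after this count was known, and expression was not measured here, so it cannot decide the question. Expression as a cause therefore stays open. Ribosomal protein genes stood above random (10 of 35 against 4.16) and olfactory receptors far below (3 of 1110 against 161), but neither decides it. Over 1 kb from every gene end the ribosomal list did not pass (3 of 35 against 1.53, ratio 1.97, adjusted p = 0.605, permutation test). With so few members expected there, that result cannot show whether the excess was absent. Olfactory receptors lie in clusters, and how well reads could be placed there was not examined. A hypothesis left open is that many of the SOX2 regions may come from astrocytes, but cell types were not separated here and the neural stem and progenitor list stood above random as well (23 of 30), so it was not tested.

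Chromosome X held 0.740 reproducible regions per Mb, while the 19 autosomes held 3.12 to 5.59. The single X of male cells would lower the tags at each site, but autosomal peaks thinned to 0.5 of their tags still left X peaks per Mb at 0.647 ± 0.0229 of the autosomes (SD, n = 3). Fewer genes on X do not account for it alone, with 0.128 regions per protein-coding gene against 0.277 on the lowest autosome. Both together remain open, because the answer depends on how gene density enters: in proportion, X peaks per gene were 0.966 ± 0.0342 of those on thinned autosomes, whereas X held 0.735 ± 0.0250 of the thinned density that a line through the autosomes gives at its gene density. That line was added, with its criterion, after the ratio per gene had met a bound of 2 SD around 1. By the same line, chromosome 7 was at 0.710 and the other autosomes at 0.879 to 1.26. Among the latter, chromosomes 12 and 18, close to X in gene density, were at 1.09 and 1.16. No explanation beyond copy number and gene density was tested.

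The third pattern is that 12253 of 27083 regions were found in 1 library only. If these were mainly peaks close to the tag threshold, strong peaks would recur, and 97.3% of the strongest score decile did, in a test that could have come out lower. Strong peaks would also recur if weak sites differed between samples, so the test cannot tell these explanations apart. Peaks above the threshold were missed too. In decile 6 of IP library 1, with scores of 20 to 23 and a threshold of 14 tags, 53.4% were found in all 3 libraries. Counting noise at the threshold remains a candidate explanation. Differences between the tissue samples stay open, since the labels do not say whether the libraries came from separate animals.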
